A study of Mus musculus with 16 samples.

How the data were processed

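RNA from the mammary gland of female mice was measured on 16 Affymetrix Mouse Genome arrays, 4 for each combination of housing (isolated or grouped from weaning) and age (15 or 20 weeks). Each array carried 45101 probe sets, short oligonucleotide groups that each report on a transcript. The deposited values are log2 expression levels made by the authors with RMA in the affy software, per the submitters' processing notes, which give no version. RMA subtracts background, forces arrays onto a common distribution of values and summarises each probe set on the log2 scale. Whether probe sets were filtered before deposit is not given in the sources used here, and the table had 0 missing values. Array data carry no read depth, so the number of arrays limits the precision.

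The values showed that the arrays of each age shared a distribution of their own. Sorted values differed by 0.0262 on average (mean absolute log2 difference) between arrays of the same age and by 0.233 between arrays of different ages. The median shift from 15 to 20 weeks over all probe sets was 0.24 on the log2 scale. It was 0.16 in 27 bacterial or unspiked control probe sets and 0.14 in 18 hybridization controls, which are not made by the mouse. Each age was therefore treated as if processed in a separate run, which no label records. Age and run cannot be told apart, and every age difference below carries that limit.

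Probe sets were named through the platform's gene table. Of all probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not listed in it, and 64 were Affymetrix controls. Entrez identifiers of 34754 single-symbol probe sets were found in the RefSeq table of assembly GRCm38.p6, used only for names, and 0 symbols changed. For each of 18193 genes, the probe set with the highest mean over the 16 arrays among those with 1 symbol was tested, and 9012 genes had more than 1 probe set. No filter on dim probe sets was applied. Probe sets without a single symbol were tested apart.

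Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Each comparison of 2 groups was fitted on its own 8 arrays. The housing difference over both ages and the housing by age interaction were fitted on all 16 arrays. There all groups share a single estimate of the spread, although some genes varied more at 20 weeks. Standard errors (SE) come from these fits, and group values are means with standard deviations (SD) over 4 arrays. The labels number the arrays of a group but do not say outright that each came from a separate mouse, so p-values measure the spread between these samples.

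Before the data were examined, 25 gene lists of pathways, cell types and responses were fixed, with 375 members, of which 345 were measured. The lists were tested with camera at a preset inter-gene correlation of 0.01, which asks whether list members shifted relative to the other genes. Adjustment was over the lists of a comparison. The fatty acid synthesis and glycolysis lists were written with the knowledge that a publication on these arrays reported genes of these pathways, so they are not independent evidence of a direction. For each list, members past the threshold were counted with adjustment over all genes and over the list alone. Array means of a list were compared with two-sided exact permutation tests, for which 35 splits of 8 arrays exist and 0.0286 is the smallest p.

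Named genes followed a rule fixed beforehand. In each comparison of 2 groups, and for housing over both ages, it takes the 10 largest increases and the 10 largest decreases among genes that passed. Where fewer than 5 passed in a direction, it takes the 5 genes with the smallest p in that direction. For the interaction it takes the 3 genes with the smallest p. It adds up to 4 members with the smallest p from each list described, and Acaca, Acly and Hk2 whatever their p.

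The alternatives were quantile normalization or cyclic loess over the arrays of a fit, filters at the 40th percentile or the median of gene levels, another probe set per gene or every probe set, and eBayes without trend or with a robust prior. Array weights (limma with statmod 1.5.0), a threshold of 0.1, the replicate number as a block, all 16 arrays in each fit, estimated inter-gene correlations, the fry test, Spearman correlation and leaving out each array were also run. After the data were seen, exact permutation tests of list means and the 3' to 5' difference of the actin or the Gapdh control probe sets as a covariate were added.

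The fits were tested on simulated data with the gene means and spreads of these arrays and with genes changed by 0.5, 1 or 2 on the log2 scale. For housing at 15 weeks, 55 of 66 genes shifted by 0.5 and 64 of 67 shifted by 1 on the log2 scale were recovered, with 11 false among 197 calls over 18193 genes. For housing at 20 weeks the recovered numbers were 40 of 66 and 61 of 67, with 2 false among 170 calls. Simulated genes varied independently, which real genes do not. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.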

Results

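The series compared mammary glands of female FVB/N mice that carry the SV40 large T antigen under the C3(1) promoter, a transgene that gives rise to mammary tumours. Mice were housed alone or with other females after weaning, and RNA was taken from the thoracic gland at 15 or 20 weeks of age. All were killed at the same point of the dark phase and in estrus, per the labels' protocols. There were 4 arrays each of grouped and isolated mice at 15 weeks and 4 each at 20 weeks. Array medians lay between 8.09 and 8.11 (log2) at 15 weeks and between 8.31 and 8.34 at 20 weeks. No arrays of a group were duplicates, as the SD of the difference between a pair was 0.111 or more on the log2 scale. The whole gland was used, so each value mixes epithelium, fat, stroma, immune cells, skeletal muscle and any tumour present. The skeletal muscle list had group means between 13.01 and 13.55 (log2), the highest of the lists.

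The first comparison asked which transcripts differed with housing at 15 weeks. Transcripts of 3 mast cell proteases were lower in isolated mice. The protease Mcpt4 was 1.68-fold lower (log2 difference -0.75, SE 0.08, adjusted p = 0.0106), the carboxypeptidase Cpa3 1.64-fold lower (-0.71, SE 0.07, adjusted p = 0.0106) and the tryptase Tpsb2 1.41-fold lower (-0.49, SE 0.05, adjusted p = 0.0106). The level of Mcpt4 was 10.4 ± 0.12 (SD, n = 4 arrays) in grouped and 9.65 ± 0.09 in isolated mice, and for each of these genes every isolated array lay below every grouped array. The macrophage list moved the same way (mean -0.33). Tpsb2 has a relative in the tryptase family, Tpsab1, and whether its probe set reads Tpsb2 alone was not tested. Of other mast cell granule genes, chosen after the proteases were seen, Cma1 (-0.51, adjusted p = 0.126) and Tpsab1 (-0.29, adjusted p = 0.44) did not pass, and Hdc differed by 0.2 the other way. The chemokine Cxcl12 was also lower (-0.64, SE 0.08, adjusted p = 0.0348), but only 1 of its 3 probe sets had that sign. Higher in isolated mice were Sprr2f, a small proline-rich protein of squamous epithelium with close relatives (0.97, SE 0.12, adjusted p = 0.025), and the kinase gene Sbk1 (0.77, SE 0.1, adjusted p = 0.025). Sprr2f lay at 5.62 to 6.27 in grouped and 6.7 to 6.99 in isolated arrays, where the arrays' lower quartiles were 6.76 to 6.79, so it was not shown to exceed background and its fold depends on that level. The sorting receptor Sorcs2 (0.64, SE 0.07, adjusted p = 0.0106) and Ido1, which degrades tryptophan (0.65, SE 0.09, adjusted p = 0.0488), were higher too. Pgm3 (0.55, adjusted p = 0.0584) and Aspn (-0.54, adjusted p = 0.0613) came next and did not pass.

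In all, 8 of 18193 genes passed at 15 weeks, 4 higher and 4 lower, and 1764 had an unadjusted p under 0.05. The count changed when single arrays were left out, which also leaves fewer arrays to estimate the spread. The log2 differences of the 3 proteases moved little in those fits. Without replicate 1 or 2 of the isolated group 0 genes passed and without replicate 3 of it 2, while without grouped replicate 1, 2 or 3 there were 16, 1 and 31. Mcpt4, Cpa3 and Tpsb2 missed the threshold without grouped replicate 2 (adjusted p = 0.0663 for each) or isolated replicate 1 (0.0539, 0.0539 and 0.0706) or 2 (0.0601 for each), and Mcpt4 (0.0552) and Tpsb2 (0.0646) without isolated replicate 3, with log2 differences between -0.78 and -0.47. With the arrays of 20 weeks in the same fit 2 genes passed, and these 3 did not (adjusted p = 0.643, 0.623 and 0.602). That fit pools the wider spread at 20 weeks, where the SD of Mcpt4 was 1.26 in grouped and 0.73 in isolated arrays. With the 3' minus 5' difference of the Gapdh control probe sets as a covariate, an alternative added after the data were seen, 2 genes passed and these 3 did not: Mcpt4 differed by -0.65 (SE 0.12, adjusted p = 0.735), Cpa3 by -0.63 (SE 0.12, adjusted p = 0.735) and Tpsb2 by -0.45 (SE 0.09, adjusted p = 0.843), each a smaller difference with a wider SE. Their lowest adjusted p over the alternatives run were 0.00115, 0.00165 and 0.00165, and those with this covariate were the highest. The other 5 genes lost their calls in several alternatives too: Ido1 in 13 of 20 (adjusted p from 0.00621 to 0.388, 0.067 after quantile normalization), Cxcl12 in 11 of 22 (0.00115 to 0.735), Sbk1 in 10 of 22 (0.00666 to 1), Sprr2f in 6 of 20 (0.00286 to 0.167) and Sorcs2 in 6 of 21 (0.00115 to 0.947).

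**Figure D1:**
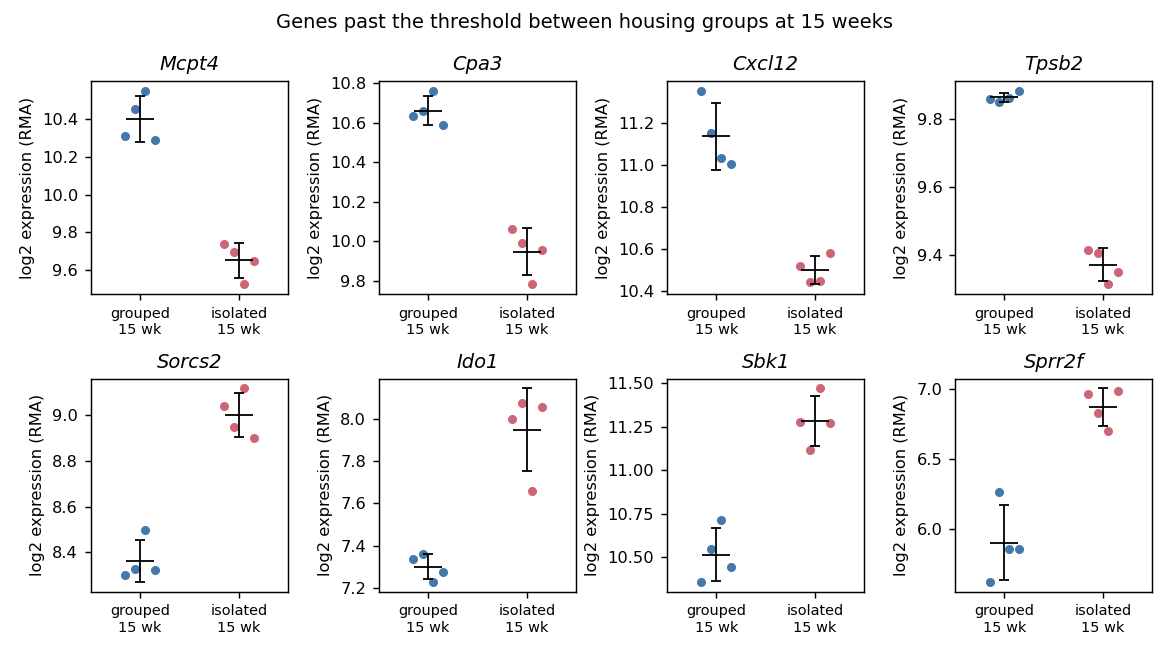
Expression (log2, RMA) of the 8 genes that passed between housing groups at 15 weeks, one point per array, with the mean and SD of 4 arrays per group. For Mcpt4 the grouped arrays lie between 10.29 and 10.55 and the isolated arrays between 9.53 and 9.74, and the groups are separate in each panel.

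Lipid synthesis genes lay higher in isolated mice at 15 weeks. Of 23 measured members of the fatty acid synthesis list, 21 had a positive difference, with a median of 0.32 on the log2 scale (camera adjusted p = 1.04e-09, but adjusted p = 0.753 with an estimated correlation). None passed over all genes, and 2 were higher when adjusted over the list alone, a list that is not independent evidence here. Acly, which makes cytosolic acetyl-CoA, differed by 0.47 (SE 0.15, adjusted p = 0.381), Acaca, which makes malonyl-CoA, by 0.45 (SE 0.19, adjusted p = 0.492) and the desaturase gene Scd2 by 0.53 (SE 0.1, adjusted p = 0.147). The transcription factor gene Mlxipl differed by 0.61 (SE 0.12, adjusted p = 0.163) and Lpin1 by 0.4 (SE 0.13). The list means were 12.27 ± 0.29 (SD) in grouped and 12.58 ± 0.08 in isolated arrays, which an exact permutation test did not separate (p = 0.0857). Without grouped replicate 1 the mean difference net of all genes was 0.19 for this list, from 0.33, and 0.11 for cholesterol synthesis, from 0.19, while Acaca differed by 0.23 and Acly by 0.31. With the probe set of largest variance Acaca differed by 0.07. With the Gapdh control as a covariate Lpin1 differed by 0.16 and Hk2 by 0.25. Of 18 cholesterol synthesis genes 15 were positive (median 0.16, camera adjusted p = 6.82e-05), among them Dhcr7 at 0.45 (SE 0.09) and Lss at 0.38 (SE 0.09), with 4 higher when adjusted over the list alone. Glycolysis genes, a list that is not independent evidence either, had a median of 0.09 (12 of 15 positive, adjusted p = 0.029), with Hk2 at 0.48 (SE 0.11, adjusted p = 0.261) and 1 gene higher adjusted over the list alone. For both lists adjusted p = 0.753 with an estimated correlation. The glycolysis call, from a mean of 0.1 net of all genes, was lost without grouped replicate 2 (0.05) or isolated replicate 2 (0.1) or 4 (0.1), and the mean was 0.17 after cyclic loess. With the actin control as a covariate it was 0.16, and with that of Gapdh it was -0.02 (adjusted p = 0.86), so the call was lost and the direction turned.

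Macrophage markers lay lower in isolated mice at 15 weeks, in 14 of 15 genes, with a median of -0.37 (camera adjusted p = 8.97e-10, adjusted p = 0.753 with an estimated correlation). The largest gap among the 4 members named was that of the scavenger receptor Cd163 (-0.71, SE 0.16, adjusted p = 0.256), followed by Tyrobp (-0.47, SE 0.1), Fcgr3 (-0.45, SE 0.13) and Mrc1 (-0.4, SE 0.11). None passed over all genes, and 12 were lower when adjusted over the list alone. With the Gapdh control as a covariate the list kept its call, but its mean net of all genes went from -0.32 to -0.17, and Cd163 differed by -0.23, Fcgr3 by -0.13 and Mrc1 by -0.19. The 4 isolated arrays all had a lower list mean than the 4 grouped arrays (exact permutation p = 0.0286). B cell and plasma cell markers (median -0.3, adjusted p = 0.0231) and T cell markers (-0.24, adjusted p = 0.0323) were called lower, with Jchain at -1.01 (SE 0.18, adjusted p = 0.101) and Cd3g at -0.91 (SE 0.44). Grouped replicate 1 had a B cell list mean of 9.01 against 7.79 in the other grouped arrays, and a T cell list mean of 8.55 against 7.76. Without it both calls were lost, and the mean difference net of all genes was -0.03 for B cells, from -0.33, and -0.05 for T cells, from -0.25, while Cd3g differed by -0.33. Both calls were also lost without isolated replicate 4 (-0.33 and -0.25), and that of T cells without isolated replicate 2 (-0.24). The actin control as a covariate ended both (-0.2 and -0.15, adjusted p = 0.129 and 0.143), and with that of Gapdh they were kept at -0.92 and -0.58, with Cd3g at -1.92. Fibroblast and matrix genes were called lower (median -0.08, 14 of 14 negative, adjusted p = 0.0431), with Pdgfra at -0.31 and Dcn at -0.24. That call was lost without grouped replicate 1, where the mean net of all genes was -0.01, from -0.09, and without isolated replicate 1 (-0.07) or 3 (-0.05). It was lost too after cyclic loess (-0.02, adjusted p = 0.656) and with the filter at the 40th percentile (-0.07, adjusted p = 0.179), and that of T cells with the probe set of largest variance (-0.26, adjusted p = 0.0531). The actin covariate ended the fibroblast call too (-0.03, adjusted p = 0.584), while with that of Gapdh it was kept at -0.13, with Pdgfra at -0.19 and Dcn at -0.14. These 3 lists had adjusted p = 0.753 with an estimated correlation, and 1 B cell gene, 0 T cell genes and 0 fibroblast genes were lower adjusted over the list alone.

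Smaller upward calls at 15 weeks were those of endothelial (median 0.15, 9 of 12 positive), skeletal muscle (0.08, 16 of 17), luminal epithelial (0.07, 11 of 16) and Schwann cell markers (0.08, 5 of 5). Examples were Kdr at 0.27, Myh2 at 0.99, Krt8 at 0.19 and Cdh19 at 0.24 on the log2 scale, none of which passed. With an estimated correlation adjusted p = 0.753 for these lists except skeletal muscle (0.83), and 1 Schwann cell gene and 0 genes of the other 3 lists passed adjusted over the list alone. Each of these calls was lost without some single arrays, with means net of all genes as follows. Endothelium (0.15) had 0.08 without grouped replicate 2, and kept its call at 0.23 without grouped replicate 3. Luminal epithelium (0.11) had 0.09, 0.1 and 0.1 without grouped replicate 1 or 3 or isolated replicate 4. Skeletal muscle (0.17) had 0.08, 0.17, 0.13 and 0.1 without grouped replicate 2 or 3 or isolated replicate 2 or 4. Schwann cells (0.12) had 0.12, 0.06 and 0.09 without grouped replicate 1 or 4 or isolated replicate 3. With the probe set of largest variance the luminal (0.09, adjusted p = 0.0531) and Schwann cell (0.13, adjusted p = 0.0698) calls were lost, and after cyclic loess skeletal muscle had 0.26. With the Gapdh control as a covariate endothelium turned to -0.1 (adjusted p = 0.0715), the calls of skeletal muscle (0.07) and Schwann cells (0.02) were lost, luminal epithelium had 0.17, and Kdr differed by 0.02 and Cdh19 by 0.1. With that of actin skeletal muscle had 0.31 and the Schwann cell call was lost (0.08). Altogether 11 of 25 lists passed with the preset correlation, 7 up and 4 down, and 0 with estimated correlations. Without grouped replicate 1 it was 7 and without isolated replicate 4 it was 6. Lists of glucocorticoid response (median -0.09, adjusted p = 0.124), cell cycle (-0.03, adjusted p = 0.547), p53 target, milk, adipocyte, fatty acid oxidation, basal cell, keratinocyte, red blood cell, interferon, clock, immediate early and hypoxia genes were not called. As a sign of RNA quality, the 3' minus 5' difference of the Gapdh control probe sets was -0.01 ± 0.02 (SD) in isolated and -0.06 ± 0.02 in grouped arrays (exact permutation p = 0.0571), and that of actin was 0.28 ± 0.03 and 0.26 ± 0.03 (p = 0.257).

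At 20 weeks, transcripts of 2 casein genes were lower in isolated mice. Csn2, which encodes beta-casein, fell 19.1-fold (log2 difference -4.26, SE 0.33, adjusted p = 0.00671), from 11.16 ± 0.34 (SD, n = 4) in grouped to 6.9 ± 0.75 in isolated arrays. Csn1s1, an alpha-casein gene, fell 1.92-fold (-0.94, SE 0.09, adjusted p = 0.0163), but its call held in 14 of 22 alternatives (adjusted p 0.00737 to 0.137) and ended with the replicate number as a block (0.057) and with all 16 arrays in the fit (0.122). Csn1s2a differed by -2.85 (SE 0.35, 7.23-fold) without passing (adjusted p = 0.11), although its groups did not overlap either, and 4 of its 5 probe sets had that sign. Csn3, which encodes kappa-casein and was singled out after its values were seen, differed by -0.18 (SE 0.25, adjusted p = 0.839), and its groups overlapped. The milk genes Wap and Lalba, also singled out after their values were seen, were lower in every isolated array without passing. Wap lay at 7.5 to 7.67 in isolated and 7.9 to 8.19 in grouped arrays, and Lalba at 8.54 to 8.75 and 8.86 to 8.95. The isolated levels of Csn2 and Csn1s2a (mean 6.22) lay near or below the lower quartile of the arrays' values, 6.98 to 7.04, and were not shown to exceed background, so their folds depend on that level. Of 13 milk genes 11 were negative (median -0.11, camera adjusted p = 4.06e-07, adjusted p = 0.3 with an estimated correlation), and 5 were lower adjusted over the list alone. Csn2 and Csn1s1 were the only ones of 18193 that passed, 0 higher and 2 lower, with 1545 at an unadjusted p under 0.05. Without grouped replicate 2 or 4 the count was 0, without grouped replicate 3 or isolated replicate 2 or 3 it was 1, and without isolated replicate 4 it was 136, 10 higher and 126 lower.

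**Figure D2:**
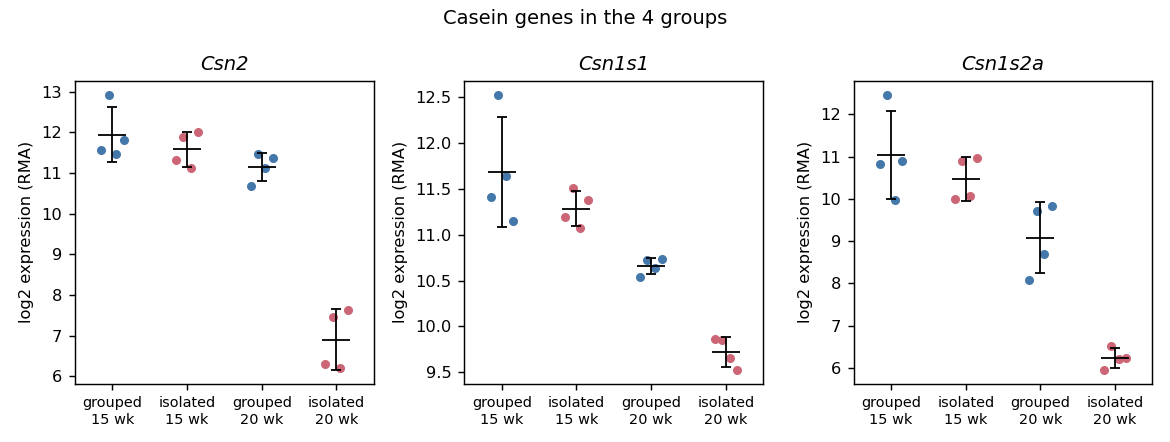
Expression (log2, RMA) of 3 casein genes, one point per array, with the mean and SD of 4 arrays in each of the 4 groups. Csn2 lies between 6.21 and 7.64 in isolated arrays at 20 weeks and between 10.69 and 11.46 in grouped arrays at 20 weeks, and levels at the 2 ages follow different value distributions.

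Adipose genes lay lower in isolated mice at 20 weeks. Of 15 white adipocyte markers 15 were negative, with a median of -0.68 (camera adjusted p = 7.98e-11, adjusted p = 0.352 with an estimated correlation), among them the hormone genes Retn at -0.9 (SE 0.2, adjusted p = 0.429) and Adipoq at -0.92 (SE 0.24, adjusted p = 0.455). The fatty acid synthesis list was negative in 23 of 23 genes, with a median of -0.61 (adjusted p = 1.14e-11, adjusted p = 0.352 with an estimated correlation). Its members Dgat2 (-1.04, SE 0.28), Fasn (-0.75, SE 0.25), Acaca (-0.82, SE 0.28, adjusted p = 0.567) and Acly (-0.62, SE 0.25, adjusted p = 0.577) did not pass, and with the probe set of largest variance Acaca differed by -0.31. Adjusted over the list alone, 10 members of each list were lower, and the fatty acid synthesis list is again not independent evidence. The array means overlapped, because isolated replicate 4 had a fatty acid synthesis mean of 12.03 against 10.95, 11.14 and 11.11 in the other isolated arrays and 11.71 to 12.03 in grouped arrays (exact permutation p = 0.114). Hk2 differed by -0.56 (SE 0.3, adjusted p = 0.627), by -0.34 without isolated replicate 1 and by -0.36 with the actin control as a covariate, and the glycolysis list was not called (median -0.08, adjusted p = 0.0949).

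Matrix and macrophage genes lay higher in isolated mice at 20 weeks. The array means overlapped: grouped replicate 3 (macrophages 11.38, matrix 12.66) lay with the isolated arrays and isolated replicate 1 (10.66 and 12.17) nearer the grouped ones, and exact permutation gave p = 0.143 and 0.114. Fibroblast and matrix genes were positive in 14 of 14 (median 0.35, adjusted p = 9.22e-08), with Lox, which crosslinks collagen, at 1.0 (SE 0.22, adjusted p = 0.422), and macrophage markers in 15 of 15 (median 0.53, adjusted p = 1.67e-07), with Tyrobp at 0.6 (SE 0.23). Interferon response genes were positive in 11 of 11 (median 0.36, adjusted p = 4.06e-07), such as Ifit1 at 0.45 (SE 0.16, 0.29 without isolated replicate 4), and hypoxia genes in 8 of 10 (0.26, adjusted p = 0.0227), such as Vegfa at 0.32. With an estimated correlation adjusted p = 0.352 for the first 3 lists and 0.405 for hypoxia, and adjusted over the list alone 1 fibroblast gene and 0 genes of the other 3 lists passed. The hypoxia call was lost without grouped replicate 3 or isolated replicate 2 or 3, with means net of all genes of 0.12, 0.08 and 0.12, from 0.16, and with the filter at the 40th percentile (0.14, adjusted p = 0.0548). The genes with the smallest p among those higher were Timp1, an inhibitor of matrix proteases (0.75, SE 0.1), Ckap4, Bst1 (0.92, SE 0.13), Adam12 and Col5a3, with adjusted p from 0.117 to 0.144. Il17b (-0.4) and Car8 (-0.55) followed the caseins among those lower, both at adjusted p = 0.144.

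Further lists called lower at 20 weeks were skeletal muscle (median -0.53, 17 of 17 negative), endothelial (-0.34, 12 of 12), fatty acid oxidation (-0.36, 17 of 18), luminal epithelium (-0.12, 15 of 16) and the circadian clock (-0.15, 11 of 15). Named members were Myh2 at -1.1, Cdh5 at -0.56, Hadh at -0.62, Foxa1 at -0.92 and the clock output gene Dbp at -0.32, none of which passed. With an estimated correlation adjusted p = 0.352 for skeletal muscle and the clock, 0.405 for endothelium and luminal epithelium and 0.581 for fatty acid oxidation. Adjusted over the list alone, 3 muscle, 2 luminal, 4 clock, 0 endothelial and 0 oxidation genes were lower. For fatty acid oxidation isolated replicate 4 (12.02) lay above all 4 grouped arrays (11.23 to 11.79) and isolated replicate 1 (10.47) far below (exact permutation p = 0.343). Without isolated replicate 1 its call was lost and the mean net of all genes was -0.12, from -0.35, and without isolated replicate 4 it was -0.62, while Hadh differed by -0.41 without isolated replicate 1. The actin control as a covariate ended that call (-0.18, adjusted p = 0.167) and took skeletal muscle to -0.35. Without isolated replicate 1 skeletal muscle also went from -0.54 to -0.35 and endothelium from -0.35 to -0.22. The clock call was lost without grouped replicate 2 or 4 or isolated replicate 3 (-0.07, -0.09 and -0.08, from -0.09) and with the probe set of largest variance (-0.06, adjusted p = 0.235). In all 12 of 25 lists passed with the preset correlation, 4 up and 8 down, and 0 with estimated correlations.

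**Figure D3:**
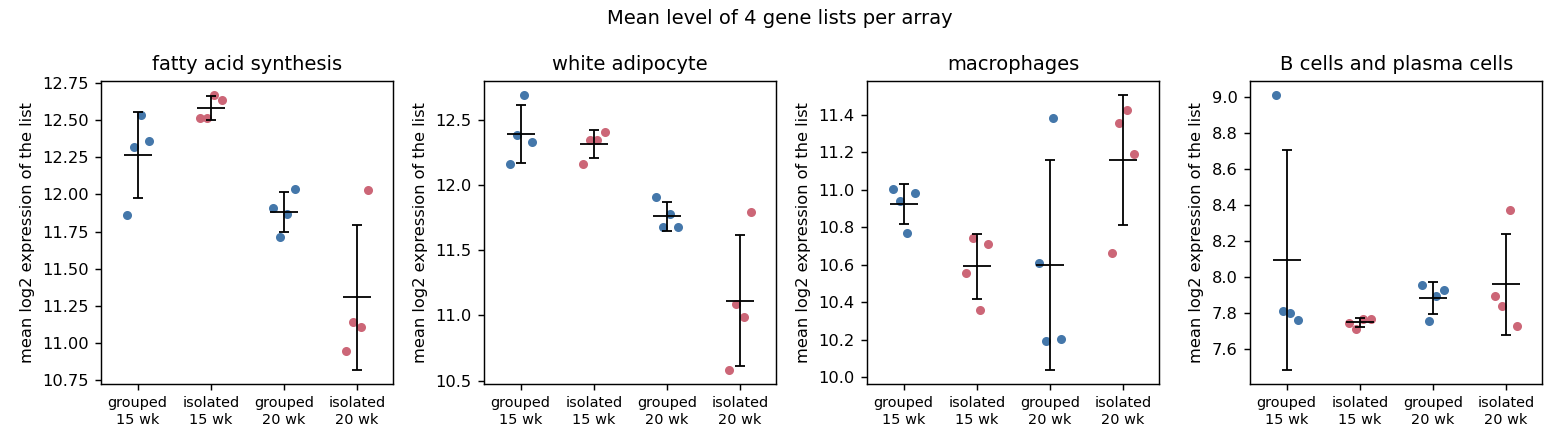
Mean expression (log2, RMA) of 4 gene lists, one point per array, with the mean and SD of 4 arrays in each of the 4 groups. Isolated replicate 4 at 20 weeks lies at 12.03 for fatty acid synthesis, and grouped replicate 1 at 15 weeks at 9.01 for B cells and plasma cells, each apart from the rest of its group.

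The housing difference itself was then compared between ages. The interaction (difference at 20 weeks minus that at 15 weeks) passed for Csn2 (-3.91, SE 0.5, adjusted p = 0.0158) and Sprr2f (-1.07, SE 0.15, adjusted p = 0.0352), and not for Dusp26 (-0.53, adjusted p = 0.127). Csn2 kept that call in 23 of 28 alternatives (adjusted p 0.000984 to 0.0697) and Sprr2f, which lay near background, in 16 of 26 (0.000984 to 0.139). Sprr2f also missed the threshold without grouped replicate 4 at 15 weeks (-1.05) or isolated replicate 2 at 20 weeks (-1.06). An unadjusted p under 0.05 was seen for 2313 genes. Fatty acid synthesis genes had a more negative housing difference at 20 weeks in 23 of 23 genes (median -0.98, camera adjusted p = 1.42e-15), and macrophage genes a more positive one in 15 of 15 (median 0.91, adjusted p = 5.48e-10). Adjusted over the list alone, 19 and 12 of their genes passed, and 0 over all genes. In total 15 lists were called, 5 up and 10 down, and 0 with estimated correlations, where the adjusted p of both lists was 0.368. Without isolated replicate 4 or grouped replicate 3 at 20 weeks, or grouped replicate 3 at 15 weeks, 139, 86 and 13 genes passed, and without isolated replicate 1 at 20 weeks 5. Leaving out grouped replicate 1, isolated replicate 2 or 4 at 15 weeks, or grouped replicate 2 or 4 at 20 weeks, gave 0, and isolated replicate 1 at 15 weeks or 3 at 20 weeks gave 1.

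Across 18193 genes the housing differences at the 2 ages had a Pearson correlation of -0.28, and 46% of genes had the same sign. With housing labels shuffled within each age, 13 of 100 draws gave a correlation as large in size, so the value was not separable from chance. Genes are not independent replicates. Over both ages, Csn2 was the only gene that passed (-2.3, SE 0.25, adjusted p = 0.00183). Pgm3 (0.31, adjusted p = 0.0726), Col5a3 (0.43, adjusted p = 0.0726) and Sncg (-0.71, adjusted p = 0.0971) came closest of the others, ahead of Sprr2f, Padi4 and Has2 among those higher and Nnat, Klhl2 and Csn1s2a among those lower. White adipocyte genes (median -0.41, 15 of 15 negative, 7 lower adjusted over the list alone) and interferon response genes (0.19, 11 of 11 positive, 0 adjusted over the list alone) were among 10 of 25 lists called over both ages, 5 up and 5 down. With an estimated correlation adjusted p = 0.6 for both and 0 lists were called. Without isolated replicate 4 at 15 weeks 6 lists were called. The count of genes was 50 without isolated replicate 4 at 20 weeks and 6 without grouped replicate 1 at 15 weeks. It was 3 without grouped replicate 3 at 20 weeks, and 2 without grouped replicate 2 or 3 at 15 weeks or grouped replicate 2 or isolated replicate 2 at 20 weeks.

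**Figure D4:**
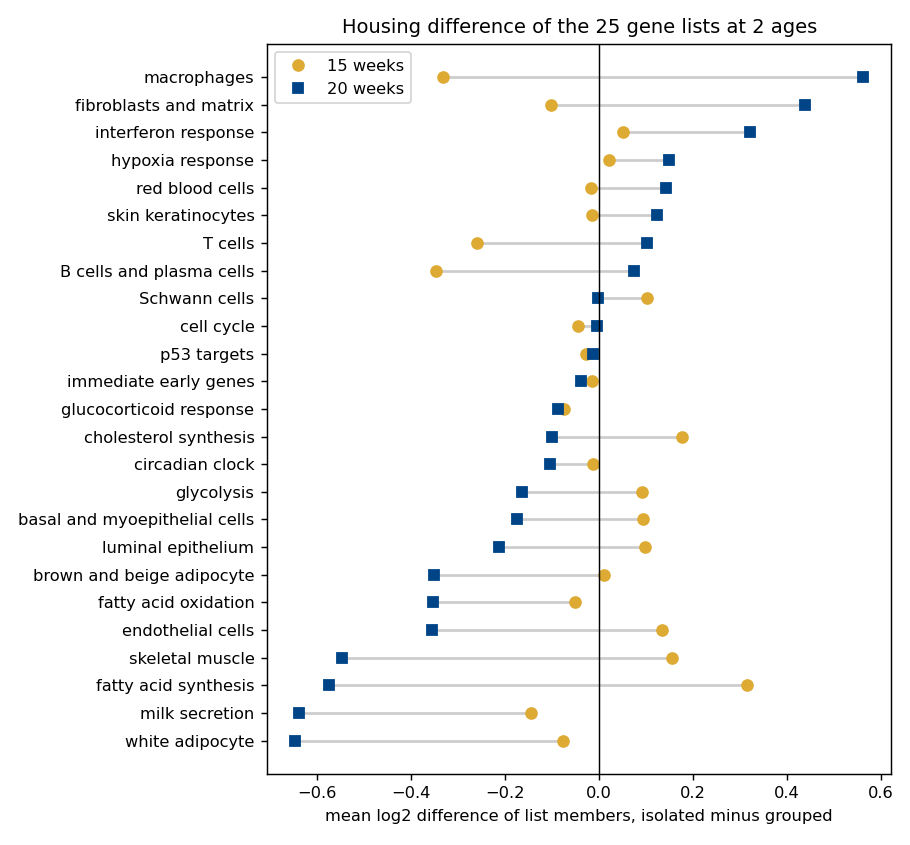
Mean log2 difference (isolated minus grouped) over the members of each of the 25 gene lists, as circles at 15 weeks and squares at 20 weeks. The fatty acid synthesis list lies at 0.31 and -0.57 and the macrophage list at -0.33 and 0.56.

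With age, casein genes and several lipid genes fell in isolated mice relative to the general shift between ages. The milk list as a whole was mixed in the deposited values, with 7 of 13 genes negative, 5 lower and 1 higher past the threshold (camera adjusted p = 1.04e-05, adjusted p = 0.35 with an estimated correlation). Those signs and counts carry the shift, so they can understate falls relative to the other genes. The fibroblast and matrix list was not called (median net of the shift 0.09, adjusted p = 0.978), although Col8a1 and Col8a2 were among the largest increases. That shift, which cannot be told apart from the processing run, had a median of 0.24 over genes in isolated and 0.23 in grouped mice, and the differences given here are net of it. In isolated mice Csn2 (-4.93), Csn1s2a (-4.49), the transferase gene B3galt2 (-2.99), Sycp3 (-2.81), Ptger3 (-2.67), Acss2 (-2.59), Acaa1b (-2.53), Ces1f (-2.43), Acacb (-2.37) and Amy1 (-2.31) were the 10 largest decreases. The largest increases were C1qtnf3 (2.6), Bst1 (2.52), the collagenase gene Mmp13 (2.38), Tchh (2.24), Cxcl5 (2.2), Col8a1 (2.18), Tnfrsf11b (2.17), S100a8 (2.08), Prg4 (1.91) and Col8a2 (1.82). Tchh rested on isolated replicate 3 at 20 weeks, which had 10.59 against 6.67 to 6.77, and without it the deposited difference went from 2.48 to 1.51, below that of Col8a2 and Prg4. Exact sizes and order are uncertain where a gene was not shown to exceed background. Of the 20 genes named here in each housing, 10 had at least 1 array below its lower quartile at either age, among them Cxcl5, Htra4, Dsg1a and Megf10 in all 4 grouped arrays at 15 weeks, Ear3 in all 4 at 20 weeks, Cxcl5 and Tchh in all 4 isolated arrays at 15 weeks and Csn1s2a in all 4 at 20 weeks. B3galt2 and Sycp3 were below it in 3 and Csn2 in 2 isolated arrays at 20 weeks. In group-housed mice Cxcl5 (1.78), Myl2 (1.78), Htra4 (1.78), Bst1 (1.77), Dsg1a (1.67), Tnnc1 (1.61), Megf10 (1.6), Fgfbp1 (1.51), Tnfrsf11b (1.49) and Col8a1 (1.45) increased most. Csn1s2a (-2.19), Retnla (-2.13), Ear3 (-2.06), Inmt (-2.03), Akr1c14 (-2.01), Mcpt4 (-2.0), B3galt2 (-1.98), Prdm8 (-1.9), Sycp3 (-1.88) and Igfbp6 (-1.81) decreased most. All of these passed as deposited and after quantile normalization of the 8 arrays together.

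By list, white adipocyte genes were lower at 20 weeks, with a median net of the shift of -1.57 in isolated and -0.82 in grouped mice (14 and 13 of 15 lower adjusted over the list alone). The same held for fatty acid synthesis (-1.5 and -0.63) and fatty acid oxidation (-1.21 and -0.83), while cell cycle genes were higher (0.61 and 0.59, 26 of 26 past the threshold in each, over all genes and adjusted over the list alone). Unlike the medians, counts of genes here come from the deposited values, which carry the shift. In those values 10422 of 18193 genes passed as higher in isolated and 10196 in grouped mice. Adjusted over the list alone, 22 fatty acid synthesis and 16 oxidation genes were lower in isolated mice and 10 and 16 in grouped mice. Camera called these lists in both housings, among 11 lists in isolated and 10 in grouped mice, and adjusted p with an estimated correlation ranged from 0.35 for white adipocyte genes in isolated mice to 0.738 for cell cycle genes in grouped mice. In isolated mice, Me1 (-2.15), Mlxipl (-1.86), Lep (-1.84) and Retn (-1.72) were lower and Ccne1 (0.72) and Aurka (0.7) higher net of the shift. In grouped mice Aqp7 (-1.51) and Acacb (-1.31) were lower, and so were Echs1 (-1.18) and Slc25a20 (-1.1). Called lower with a deposited median just above 0 were the glycolysis (0.02) and basal cell (0.0009) lists in isolated mice and the T cell list (0.0043) in grouped mice, since camera compares with the other genes. With an estimated correlation adjusted p = 0.508, 0.35 and 0.616 for these 3 lists. The basal cell call (adjusted p = 0.0492) ended in 8 of 14 alternatives, among them without replicate 1 (-0.15) or 3 (-0.16) of 15 weeks or 1 (-0.13) or 4 (-0.19) of 20 weeks, from a mean of -0.17 net of all genes. The T cell call ended without grouped replicate 1 of 15 weeks (-0.13, from -0.33) and after cyclic loess. The number of genes past the threshold was 11362 in grouped mice (10196 higher, 1166 lower) and 12119 in isolated mice (10422 higher, 1697 lower). After quantile normalization it was 7022 (3505 higher, 3517 lower) and 9176 (4490 higher, 4686 lower), so the excess of higher genes went with the difference in value distribution between the ages.

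Probe sets with no single gene symbol were tested apart. Of 10092, 0 passed in limma for housing at 15 weeks (smallest adjusted p = 0.125) and 0 at 20 weeks (0.294), with 813 and 571 at an unadjusted p under 0.05.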

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

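The tests of the proteases against the macrophage list, of fatty acid synthesis against other lists and without single arrays, and of caseins against the luminal list were chosen after their results were seen. The actin and Gapdh covariate and mast cell marker tests were chosen after the patterns were seen but before their own results.

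Mcpt4, Cpa3 and Tpsb2 were lower in isolated mice at 15 weeks by 0.65 on average (log2 difference -0.651, exact permutation p = 0.0286). RNA quality as the whole cause was argued against. With the actin 3' to 5' difference, which differed little with housing (exact permutation p = 0.257), the largest adjusted p was 0.025. With that of Gapdh, which nearly parted the groups (exact permutation p = 0.0571), the mean difference was -0.575 (SE 0.082) against a bound of -0.325. All 3 calls then ended (adjusted p 0.735, 0.735 and 0.843), as the SE of Mcpt4 went from 0.08 to 0.123 and its difference from -0.75 to -0.649. A covariate that nearly parts the groups widens the SE whatever it measures, so these lost calls do not decide. A part from RNA quality stays open. A general loss of leukocytes stays open: a first test, which required equal falls, had argued against it (proteases minus macrophage list -0.317, exact permutation p = 0.0286), but it was replaced after that value was seen, because within the 20-week groups the proteases moved 1.73 times as far as the list, and scaled so -0.075 (SE 0.176, exact permutation p = 0.629) remained. Fewer mast cells may also explain it, as 7 other mast cell markers with a mean level of at least 7 were lower by a mean of -0.122 (exact permutation p = 0.0286). This was a smaller fall than that of the proteases, but it depends on the markers in the set, with Cma1 at -0.51 and Tpsab1 at -0.29 but Kit at 0.04, Gata2 at -0.01 and Hdc at 0.2. Of the dimmer markers left out, Slc18a2 (-0.46), Rgs13 (-0.21) and Mrgprb1 (-0.19) were lower without passing, and Fcer1a (0.01) was not lower. A response of mast cells to housing was not tested, and at 20 weeks the proteases differed by 0.626 the other way (exact permutation p = 0.314).

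The fatty acid synthesis list lay higher in isolated mice at 15 weeks and lower at 20 weeks, but neither call held with an estimated correlation (adjusted p = 0.753 and 0.352) or in exact permutation of array means (p = 0.0857 and 0.114). At 15 weeks the list lay 0.391 higher relative to white adipocyte markers (exact permutation p = 0.0286). That test does not decide on a larger share of fat, since the list was taken up for its rise in these same arrays. The markers themselves did not rise (-0.076, exact permutation p = 0.686), which argues against a larger share of fat. A larger share of luminal cells (0.216 beyond the luminal list, exact permutation p = 0.229) and the weight of single grouped arrays (0.178 without grouped replicate 1, from 0.314) cannot be told apart from a change in the cells. The last was first read against a bound of 0.157, which 0.178 exceeds and which argued against it, and a margin of the SE (0.15) was added after that value was seen. At 20 weeks the list moved with white adipocyte markers (difference between them 0.072, exact permutation p = 0.457), which is consistent with a smaller share of adipocytes, while an effect of housing on lipid synthesis itself stays open at both ages.

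The fall of Csn2, Csn1s1 and Csn1s2a in isolated mice at 20 weeks went beyond the luminal list by -2.469 (exact permutation p = 0.0286). The genes were chosen for their falls in these same arrays, so the test could hardly come out otherwise and does not decide on fewer luminal cells. The RNA controls gave no sign of a housing difference at 20 weeks. Actin 3' minus 5' differed by 0.037 (exact permutation p = 0.4) and Gapdh by -0.008 (exact permutation p = 0.629). A covariate that differs so little could hardly take up a fall of this size, so the fits with it do not decide on RNA quality. With the actin covariate Csn2 differed by -4.108 (SE 0.342, adjusted p = 0.021). Csn1s1 then missed the threshold (-0.946, SE 0.097, adjusted p = 0.0552, range over the alternatives run 0.00737 to 0.137), with nearly the same fold and a wider SE than without it (-0.94, SE 0.09). With that of Gapdh both genes passed, Csn2 at -4.256 (SE 0.353, adjusted p = 0.0232) and Csn1s1 at -0.919 (SE 0.083, adjusted p = 0.0234). Csn3, which was left out of the test of 3 caseins, differed by -0.18 (SE 0.25). Wap and Lalba, also outside that test, lay lower in every isolated array than in every grouped one. Of the 13 milk genes 11 were negative. A loss of a secretory subset of cells and a difference in hormonal state were not tested, so the source of the fall stays open.

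Other splits of the arrays were used to judge the counts. At 15 weeks 1 of 35 splits (the real one) gave as many as 8 genes, and the highest other gave 3, so no other split matched it. With array weights, estimated anew in each split, the real split gave 494 genes and the highest other 21. The share can be no lower with 35 splits, and several counts were judged in this way, so chance was not excluded. At 20 weeks 2 of 35 gave at least 2 genes and the highest other 340, so chance was not excluded. With array weights the real split gave 4 there and the highest other 481. The split that gave 340 genes set grouped replicates 1, 2 and 4 with isolated replicate 1 against the rest, which points to a structure of the samples other than housing. For age, 1 of 35 splits reached the 11362 genes in grouped mice (highest other 1) and 1 of 35 the 12119 in isolated mice (highest other 0). No other split came near, but this does not part age from the processing run. Over both ages 9 of 100 splits gave as many as the 1 gene (highest other 950), so chance was not excluded. For the interaction 3 of 100, the real one included, gave as many as 2, but another split gave 202, so chance was not excluded there either. Counts of lists did not exceed other splits: 13 of 35 gave as many as the 11 at 15 weeks (highest other 16) and 11 of 35 as many as the 12 at 20 weeks (highest other 16). The same was seen for the 10 lists with age in grouped mice (26 of 35, highest other 14) and the 11 in isolated mice (20 of 35, highest other 19). It also held for the 10 lists over both ages (41 of 100, highest other 17) and the 15 of the interaction (6 of 100, highest other 17).

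The housing difference changed between ages for Csn2 (-3.91) and Sprr2f (-1.07). It was called by camera for 15 lists, given as mean interaction over members, where 0 lists passed with estimated correlations or with fry and 6 of 100 splits gave as many. These were fatty acid synthesis (-0.89), glycolysis (-0.26), cholesterol synthesis (-0.28), fatty acid oxidation (-0.3), white adipocyte (-0.57), luminal epithelium (-0.31) and basal cells (-0.27). Milk secretion (-0.49), skeletal muscle (-0.7), endothelial cells (-0.49), macrophages (0.9), T cells (0.36), B cells (0.42), fibroblasts and matrix (0.54) and interferon response (0.27) completed them. Net of all genes, several changed or lost their calls without single arrays, in some cases with nearly the same mean. Without grouped replicate 1 at 15 weeks B cells went from 0.42 to 0.11 and T cells from 0.36 to 0.16, and without isolated replicate 3 at 20 weeks to 0.29 and 0.23, with both calls lost. The B cell call was also lost without isolated replicate 4 at 15 weeks (0.41) or grouped replicate 2 at 20 weeks (0.37). Fatty acid oxidation went from -0.31 to -0.08 without isolated replicate 1 at 20 weeks and lost its call, as it did without grouped replicate 4 at 15 weeks (-0.26) or 3 at 20 weeks (-0.22), and to -0.58 without isolated replicate 4 at 20 weeks. Glycolysis (-0.26) lost its call without grouped replicate 2 at 15 weeks (-0.2) or isolated replicate 1 (-0.19) or 3 (-0.24) at 20 weeks, basal cells (-0.27) without grouped replicate 2 at 15 (-0.24) or 20 weeks (-0.24), and interferon response (0.27) without isolated replicate 4 at 20 weeks (0.17) or with the filter at the 40th percentile (0.24), which took milk from -0.5 to -0.95.

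In 42 of 596 groups of 4 arrays, 1 array stood apart from the other 3 relative to the group's range, where chance flags about 1 in 20 groups, or 29.8. Genes named for age alone were added to this search after the values of Tchh were seen. Values are the gap to the nearest array as a share of the group's range, so in tight groups a small gap is flagged. Aurka was flagged at 8.81 (log2) against a mean of 8.74 in the other arrays and Me1 at 13.58 against 13.49. Larger gaps were those of Tchh, at 10.59 against 6.72, and Ighm, at 11.91 against 10.35. Grouped replicate 1 at 15 weeks stood apart for Ighm (0.93), Cd3g (0.849), Car8 (0.979), Slc25a1 (0.859) and the T cell (0.887) and B cell (0.96) lists. Isolated replicate 4 at 20 weeks did so for Sbk1 (0.93), Acly (0.89), Acaca (0.903), Padi4 (0.839) and Sncg (0.877), isolated replicate 1 for Myh2 (0.921), Dcn (0.884), Il17b (0.965) and Foxa1 (0.844), and isolated replicate 3 for Cd3g (0.832) and the T cell (0.929) and immediate early (0.848) lists. Grouped arrays at 20 weeks stood apart for Il7r (0.906), Adam12 (0.876), Retn (0.859), Ifit1 (0.843) and the cholesterol synthesis (0.887) and basal cell (0.901) lists. The rest were Sorcs2 (0.88), Ccr2 (0.88) and the hypoxia list (0.895) in grouped arrays at 15 weeks, and Postn (0.901), Ccr2 (0.864) and Hlf (0.901) in isolated arrays at 15 weeks. Of the genes named for age alone, Tchh (0.974, isolated replicate 3), Megf10 (0.877, isolated replicate 1), Acss2 (0.87) and Acaa1b (0.88), both isolated replicate 4, and Htra4 (0.879) and Inmt (0.912) in grouped arrays had such an array at 20 weeks. At 15 weeks grouped replicate 1 stood apart for Col8a1 (0.86) and Acss2 (0.886), isolated replicate 1 for Col8a1 (0.84), Dsg1a (0.904) and Aurka (0.956), and isolated replicate 4 for Me1 (0.923).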

How the results depend on the processing

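The exact permutation of list means and the actin and Gapdh covariates were chosen after seeing the data. Signal over background limits dim genes, and no detection calls were used. Genes past the threshold for housing at 15 weeks numbered 4 with every probe set, 494 with array weights, 27 at a threshold of 0.1, 2 with all 16 arrays, 28 with the actin covariate and 2 with the Gapdh covariate. At 20 weeks they numbered 4 with every probe set, 4 with array weights, 8 with all 16 arrays and 1 with the actin covariate. Over both ages they were 3 above the 40th percentile, 2 with the probe set of largest variance, 137 with array weights and 4 at 0.1. For the interaction they were 1 above the 40th percentile, 1 above the median, 1 without trend and 778 with array weights. For age in grouped mice they were 7022 after quantile normalization, 7084 after cyclic loess, 6720 above the 40th percentile, 5628 above the median and 28727 with every probe set. In isolated mice they were 7764, 6618 and 30453 under the last 3 settings, where fewer genes or more probe sets were tested. Lists called were 0 in all 6 comparisons with estimated correlations. The fry test called 0 at 15 weeks, 1 at 20 weeks, 0 over both ages and 0 for the interaction, and the filter at the 40th percentile 7 at 15 weeks. The exact permutation called 0 at 15 and 0 at 20 weeks, which the design fixed unless at least 15 of the 25 lists reached its smallest p of 0.0286, and says nothing on stability. Unadjusted, 1 and 3 lists had an exact p under 0.05. With the actin covariate 7 lists were called at 15 weeks, and with that of Gapdh the direction of endothelial (-0.0992) and glycolysis (-0.016) lists reversed there. The correlation between ages was -0.344 above the median and -0.183 by Spearman. Except where construction shows it, the cause was not tested. Csn2 at 20 weeks kept its direction in 22 of 22 alternatives and its call in 20 (adjusted p 4.39e-05 to 0.0732), and Mcpt4 at 15 weeks its direction in 22 of 22 and its call in 16.

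The replicate numbers were not taken to pair the samples, since no label says so and not every same-numbered pair deviated together. The r was 0.101, -0.097, 0.359 and 0.357 at 15 weeks and 0.42, -0.164, 0.488 and -0.105 at 20 weeks, and 5 of 8 grouped arrays correlated best with their own number, a hint from the data that leaves pairing of some arrays open. With the replicate block, 17 genes passed at 15 weeks, 3 over both ages and 61 for the interaction, Csn1s1 at 20 weeks missed the threshold (adjusted p = 0.057), and no other count of calls moved by over 1.5 times.

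Leaving out each array gave 0 to 31 genes and 6 to 14 lists at 15 weeks, 0 to 136 genes and 10 to 18 lists at 20 weeks, 1 to 50 genes and 6 to 14 lists over both ages, and 0 to 139 genes and 12 to 16 lists for the interaction. For age it gave 9924 to 11288 genes and 8 to 12 lists in grouped mice and 10905 to 12155 genes and 10 to 12 lists in isolated mice. The correlation ranged from -0.355 to -0.148. The list of B cells and plasma cells, housing at 15 weeks, ranged from -0.458 without grouped replicate 4 to -0.0267 without grouped replicate 1. There the mean stayed negative, and only the direction given by camera turned (camera adjusted p = 0.892). For Ccr2 with age in grouped mice the direction reversed with the probe set of largest variance (-0.924). With fry, the tested direction reversed for milk (-0.571) and T cell (-0.331) lists with age in grouped mice and glycolysis (-0.381) and basal cell (-0.17) lists in isolated mice, whose values are relative to all genes, which fry does not use.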

Other observations

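The values below were chosen after they were seen. Lymphoid transcripts were high in 2 arrays, one of each housing. Glycam1, a mucin gene of milk and of high endothelial venules that was singled out after its values were seen, was 13.09 (log2) in grouped replicate 1 at 15 weeks and 11.54 in isolated replicate 3 at 20 weeks. Another array, grouped replicate 2 at 15 weeks, had 9.12, and the other arrays lay between 7.38 and 7.85. The B cell gene Ms4a1 was 9.51 and 8.75 in the first 2 arrays against 7.2 to 7.76 elsewhere, and the T cell gene Cd3g was 9.29 and 8.45 against 6.52 to 7.21. The list means of B cells were 9.01 and 8.37 in these arrays.

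At 20 weeks the mast cell proteases, macrophage and matrix genes were high in the same arrays, across housing. The mean of Mcpt4, Cpa3 and Tpsb2 was 10.38 in grouped replicate 3 and 10.02, 10.15 and 9.39 in isolated replicates 2, 3 and 4. It was 8.89, 8.31 and 8.32 in grouped replicates 1, 2 and 4 and 8.83 in isolated replicate 1. The macrophage list mean was 11.38 in grouped replicate 3 and 11.36, 11.43 and 11.19 in isolated replicates 2, 3 and 4, against 10.61, 10.19, 10.21 and 10.66 in the rest. The matrix list followed, with 12.66, 12.65, 12.62 and 12.77 against 12.06, 12.07, 11.67 and 12.17. These arrays are parted in the same way by the split that called 340 genes, where housing called 2.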
